A study of Mus musculus with 50 samples.

How the data were processed

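PolyA-selected RNA of 18 libraries was sequenced by the authors: 12 from knockout clones 28 and 36 (2 clones, 2 biological replicates each, at 0, 24 and 48 h without Dox) and 6 from parental floxed cells of clone 21 (2 per time). RNA integrity numbers in the labels lay between 9.1 and 10. The submitters' processing notes name STAR 2.4.1d, RSEM, DESeq 1.22.1, BWA 0.7.12-r1039, SAMtools 1.3 and bedtools 2.20.1, and both mm9 and mm10, with no role or order. Which of these made which column is not given in the sources used here. The sheet's name holds EBSeq, a tool that models expression in groups of libraries.

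The authors' deposited table has 12819 rows, 1 per gene. For each time it gives, per the file headers, a posterior probability of differential expression between 0 h and that time, a log2 fold change described as real, a yes or no mark named for a Dox effect, and an adjusted p-value. The log2 fold changes were deposited by the authors as computed from their groups. The adjusted p-values were deposited by the authors with no statement of their test or groups. No column holds values per library, so replicates, depth and expression level could not be examined, no model was fitted here, and the spread between libraries enters only through the authors' own statistics. Nothing on the precision of a single gene's change can be added to them. A deposited change was multiplied by -1 to give the later time over 0 h. No header states the direction. It was read from the order of the times in the column names and from the sign of the Cdk12 row, which was itself not called.

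A gene was called where the posterior probability was at least 0.95, a rule fixed before the data were examined for a table without libraries. Each called gene changed by at least 1.43-fold at either time, a property found in the table and not set here. Genes with a change and no posterior probability, 156 at 24 h and 358 at 48 h, stayed out of counts of calls. All genes with the Dox mark had been called at that time. The table holds 23 gene names turned into dates by a spreadsheet, and these were kept as rows and not named. Some results on single genes are not reported here. Medians over all genes were 0.01 on the log2 scale at both times, and no rescaling was made.

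Calls were counted by direction. Gene lists, 29 in number, were fixed before the data were examined, and 27 had at least 5 measured members. The list of 2-cell-like genes had 1 measured member and that of mitochondrially encoded genes 0, and neither was tested. Each list was tested in 2 ways. A two-sided Fisher's exact test compared called members that fell, and those that rose, with all other genes that carry a posterior probability. The list's median change was also set among 10000 random lists of the same size, with a two-sided permutation p. Those random lists were not matched on expression, for which the table gives no level. Benjamini-Hochberg adjustment ran over all lists of a time, over both directions for Fisher's test. Genes are not independent replicates, so these p-values describe the table and not a spread between cultures. Without unadjusted p-values per gene, no count adjusted over the list alone could be made.

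Gene names were matched to the NCBI annotation of GRCm38.p6 by symbol or unique synonym, for 12707 of 12819 rows. It served for neighbours and for genomic length from first to last annotated base, and no coordinates are printed because the build behind the RNA values is not given in the sources used here. Length was compared with change by Spearman correlation with 100000 permutations, two-sided, and by the share of calls per quartile with 95% Wilson intervals. For the comparison of times, 100 sets of 3 unchanged groups of 4 libraries were simulated, 2 of them compared with the third.

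Named genes followed a rule fixed before the data were examined. It takes Cdk12, Ccnk and Cdk13, the 10 largest rises and falls among called genes at each time without predicted or clone names, up to 4 called members per list or 2 uncalled ones, and any homologous recombination or checkpoint gene. Trp53, Gm14430, Alpk3, Foxn4, Ttc7, Cdkn1a and the genes named only in the closing section were chosen after their values were seen. Alternatives were posterior probability of at least 0.99, minimum changes of 1.5-fold and 2-fold, removal of predicted names, random lists matched on gene length and called genes alone for length. Added after the data were seen were the second deposited statistic as the call, removal of marked genes, protein-coding genes alone, and all tests on neighbouring genes and on the Dox mark.

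List tests were tested on simulated data made by shuffling the real changes over genes. With 200 genes shifted by 0.7 on the log2 scale, the median test found all 8 lists drawn from them among 12408 genes at 48 h. With no shift it found 0 of 8. Fisher's test gave the same counts. Calls of shifted genes were, however, assigned at random, far more often than in the real data and whatever the size of the shift. What Fisher's test found was thus fixed by that setting and does not measure its power. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.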

Results

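The series measured polyA-selected RNA in V6.5 mouse embryonic stem cells in which the endogenous Cdk12 gene is knocked out and a doxycycline (Dox) inducible, epitope-tagged Cdk12 transgene takes its place. Cdk12 is a cyclin-dependent kinase that, with cyclin K (Ccnk), phosphorylates the C-terminal domain of RNA polymerase II. Keeping Dox at 1 µg/mL maintains the transgene, and withdrawing it depletes Cdk12. There were 18 RNA libraries. Of these, 12 came from 2 knockout clones, numbers 28 and 36, each in duplicate at 0, 24 and 48 h without Dox, giving 4 libraries per time. The other 6 came from parental cells with floxed Cdk12 and no transgene, treated with Dox for 17 days and then harvested at the same times, 2 libraries per time, as the control for an effect of Dox itself. A further 32 chromatin immunoprecipitation and control libraries of clone 36 are not analysed here. The values come from a table of the authors' own comparisons of 0 h with each later time in the knockout clones, with 12819 rows and no column per library. No SD or number of replicates can therefore be set beside a gene, and the depth of the libraries is unknown. Changes are written as the later time over 0 h. That direction was read from the order of the times in the column names and from the sign of Cdk12, and if it were the other way every rise and fall below would be exchanged.

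The depleted gene cannot check the labels here, since its sign was used to read the direction of the changes. In the authors' deposited table the log2 change of Cdk12 was -0.61 at 24 h and -0.61 at 48 h, with posterior probabilities of differential expression of 0.0704 and 0.266, so Cdk12 was not called at either time. Transcripts of the knocked-out locus and of the transgene may both count toward this row. Its partner Ccnk stood at -0.02 at both times in the authors' deposited table, and the related kinase Cdk13 at -0.10 and -0.19. Neither was called.

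The first comparison asks which transcripts had changed 24 h after Dox withdrawal. A small set of genes fell steeply. In the authors' deposited table Duoxa1 fell by 4.84 and Duox1 by 4.53 on the log2 scale; Duox1 is a hydrogen peroxide-producing oxidase and Duoxa1 its maturation factor. Rapgef4, a cAMP-activated exchange factor, fell by 4.02 to 6.18% of its 0 h level in the authors' deposited table. The calcium-binding protein gene Pvalb fell by 4.75, Lypd1 by 3.71 and Slc44a3 by 2.68 on the log2 scale in the authors' deposited table. Transcription factor genes Ascl2 and Tfap2a fell by 2.34 and 2.32 there, and Th, which encodes tyrosine hydroxylase, by 2.09, as the authors' deposited table gives them. Rises among called genes were smaller. The largest of them without a predicted name in the authors' deposited table were Zhx3 at 1.21, Igsf9b at 1.16, Zfp750 at 1.14 and Nkx2-9 at 1.07 on the log2 scale. The histamine receptor gene Hrh1 rose by 1.00, Sox21 by 0.83 and Nfatc2 by 0.83 in the authors' deposited table. At a posterior probability of at least 0.95 the authors' deposited table called 143 of 12663 genes, of which 86 fell and 57 rose. With a minimum change of 2-fold 33 fell and 4 rose. A second deposited statistic, an adjusted p whose test and groups are not stated, called 21 genes at 0.05, of which 19 fell and 2 rose. One of these rises was the predicted gene Gm14430, which carried no posterior probability at either time and stood at 14.14 at 24 h and 13.99 at 48 h on the log2 scale, with adjusted p values of 0.0377 and 0.0197 by the authors' second statistic in the authors' deposited table. The expression level behind changes of this size is unknown here. Of the genes named above, Duox1, Duoxa1 and Ascl2 passed the second statistic at 24 h. Lypd1, Igsf9b and Hrh1 did not, with adjusted p values of 0.828, 0.107 and 0.816 by the authors' second statistic in the authors' deposited table. Since only 2 rises passed it and 1 of them was Gm14430, at most 1 of the other rises named above can have passed.

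By 48 h without Dox many more genes had changed, in near equal numbers in each direction. In the authors' deposited table Rapgef4 fell by 5.28 on the log2 scale, to 2.57% of its 0 h level. Duox1 fell by 4.78, Duoxa1 by 4.40, Lypd1 by 4.28 and Tfap2a by 3.17 in the authors' deposited table. Col6a5, a collagen chain, fell by 3.04, Slc44a3 by 2.90, the kallikrein Klk1 by 2.79, and the cyclic GMP phosphodiesterase Pde9a by 2.20 in the authors' deposited table. Pvalb carried no posterior probability at this time and so could not be called, but its log2 change was -12.27 with an adjusted p of 1.85e-10 by the authors' second statistic in the authors' deposited table. The largest rises among called genes without predicted names in the authors' deposited table were the neurogenic factor Neurod1 at 2.53, the ligand Wnt3 at 2.21, and the histone genes Hist2h3c1 at 2.17 and Hist2h2aa1 at 2.11 on the log2 scale. Both leukotriene B receptor genes rose, Ltb4r1 by 2.01 and Ltb4r2 by 1.86, as did Hoxc13 by 1.88 and the proton pump gene Atp12a by 1.80, in the authors' deposited table. At a posterior probability of at least 0.95 the authors' deposited table called 954 of 12408 genes, of which 493 fell and 461 rose. At 2-fold or more 187 fell and 145 rose. The second deposited statistic called 465 genes, 249 that fell and 216 that rose. Duox1, Duoxa1 and Klk1 passed it at 48 h. Lypd1 did not, at an adjusted p of 0.139 by the authors' second statistic in the authors' deposited table, and Col6a5 carried no value of it.

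Targets of the transcription factor p53 were the group that rose most clearly. Of 28 measured members 26 had a posterior probability at 48 h. Of these 14 were called as risen and none as fallen, where 0.966 called rises were expected (two-sided Fisher's exact p = 5.05e-14, adjusted p = 2.73e-12). Called or not, 25 members were higher than at 0 h and 3 lower. In the authors' deposited table Zfp365 rose by 1.55 and the pro-apoptotic gene Bbc3 by 1.32 on the log2 scale. The polo-like kinase gene Plk2 rose 2.82-fold and Mdm2, which encodes the ubiquitin ligase for p53, 2.33-fold in the authors' deposited table. The cell cycle inhibitor gene Cdkn1a rose by 0.76 in the authors' deposited table but did not pass the second statistic. At 24 h 2 members, Plk2 and Zfp365, were called as risen, by 0.71 and 0.63 in the authors' deposited table (Fisher's exact p = 0.00698, adjusted p = 0.188). Neither passed the second statistic at 24 h. The list's median was 0.28 at 24 h and 0.71 at 48 h, above all 10000 random lists of the same size at both times (permutation p = 0.0002, the smallest these draws can give; adjusted p = 0.0018 and 0.0009). Transcripts of p53 itself, Trp53, stood at 0.13 and 0.05 in the authors' deposited table and were not called. The authors mark 10 of the 14 p53 targets as a Dox effect, a mark whose meaning the table does not define. Without marked genes 4 of 16 members were called as risen (Fisher's exact p = 0.00142, adjusted p = 0.0383).

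**Figure D1:**
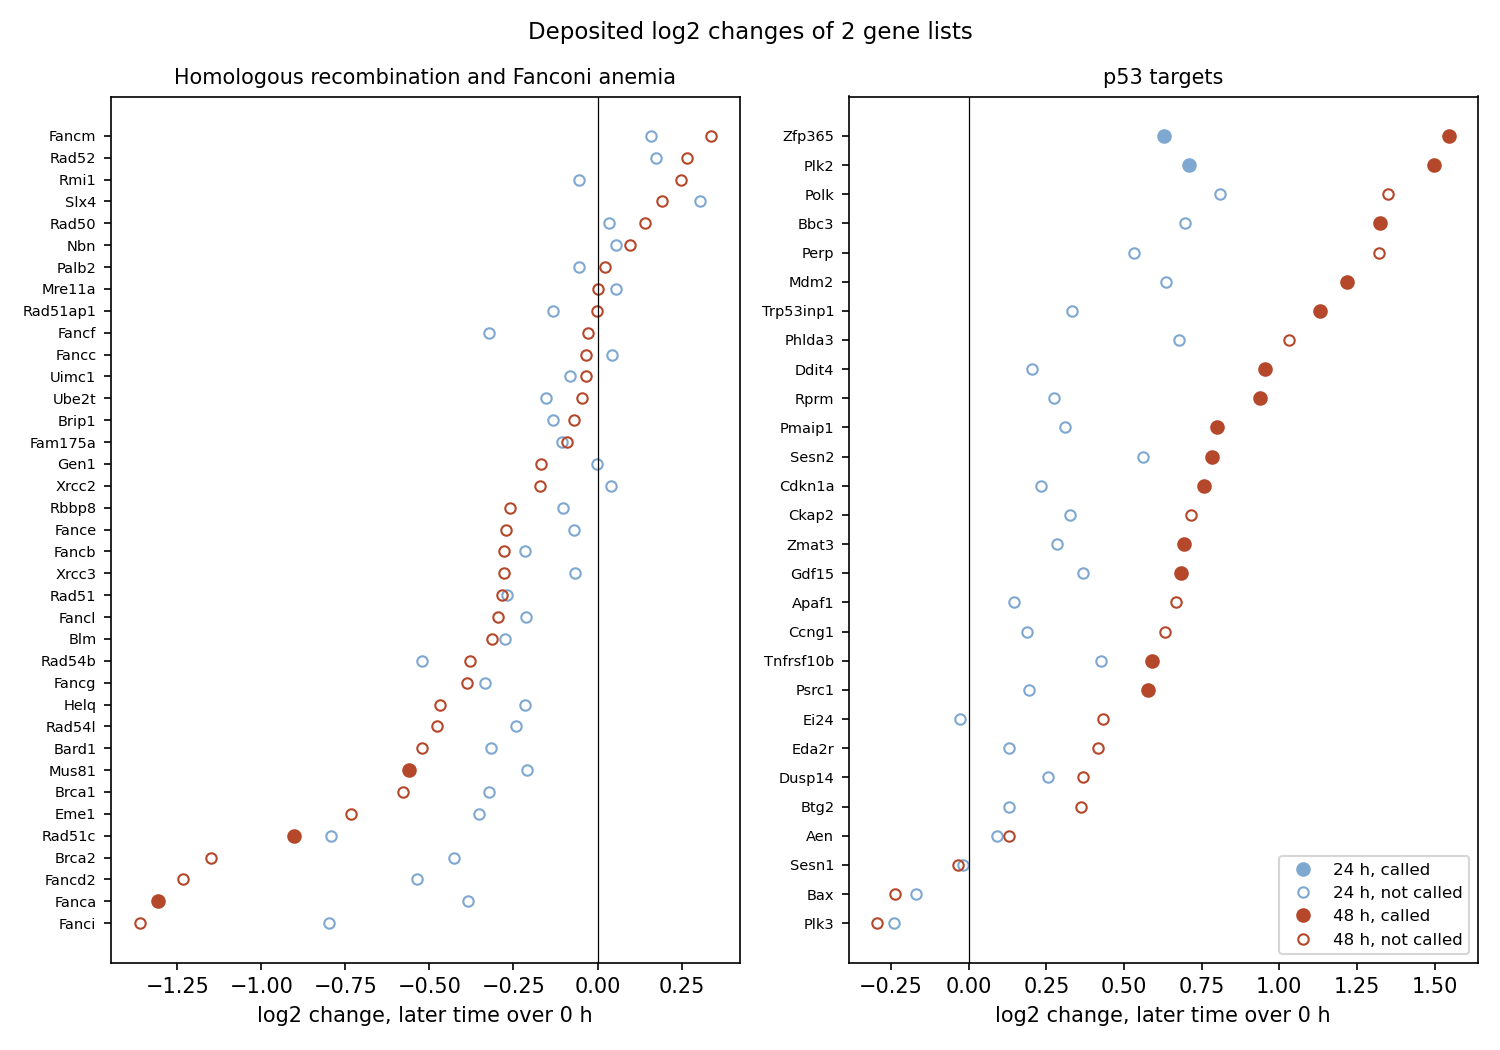
Log2 change of each measured member of 2 gene lists, later time over 0 h, as the authors' deposited table gives it, at 24 h (blue) and 48 h (red). Filled points are genes called at a posterior probability of at least 0.95: 3 repair genes, all lower, and 14 p53 targets, all higher, at 48 h.

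Homologous recombination and Fanconi anemia genes lay lower as a group while few members were called. Of 37 measured members 29 were below 0 at 24 h and 29 at 48 h. Called falls at 48 h numbered 3, against 1.43 expected of members with a posterior probability (Fisher's exact p = 0.171, adjusted p = 1). They were Fanca, which fell by 1.31, Rad51c, which fell by 0.90, and the nuclease gene Mus81, which fell by 0.56 in the authors' deposited table. Mus81 carries the authors' Dox mark, and without marked genes 2 called falls were left (Fisher's exact p = 0.328, adjusted p = 1). None was called at 24 h. The list's median was -0.15 at 24 h (permutation p over random lists = 0.001, adjusted p = 0.0054). At 48 h the median was -0.27, below all 10000 random lists, with a permutation p of 0.0002 and an adjusted p of 0.0009. Uncalled members with changes larger than that of Mus81 included Fanci at -1.36, Fancd2 at -1.23, Brca2 at -1.15, Eme1 at -0.73 and Brca1 at -0.58. Their posterior probabilities were 0.167, 0.123, 0.788, 0.146 and 0.835, in that order, in the authors' deposited table. DNA damage checkpoint genes had no called member at either time. Their median of -0.10 at 48 h lay within the range of random lists (permutation p = 0.174, adjusted p = 0.277), and Atm stood at -0.75 in the authors' deposited table.

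Other repair pathways showed few calls. Mismatch repair genes had the lowest median of any list at 48 h, -0.32 over 8 members, with no called member (permutation p = 0.0296, adjusted p = 0.0615), and Mlh3 and Exo1 stood at -1.14 and -1.04 in the authors' deposited table. In base excision repair the glycosylase genes Mutyh and Ogg1 fell by 1.10 and 0.52 at 48 h in the authors' deposited table, 2 of 20 members, with a list median of -0.03 (permutation p = 0.653). Of these 2 called genes 1 carries the authors' Dox mark. In nucleotide excision repair 1 of 18 members, Ercc5, was called as risen, by 0.92 in the authors' deposited table, and it carries the Dox mark. The list median was 0.06 (permutation p = 0.585). Non-homologous end joining had no called member, and its median was 0.01 at 48 h (permutation p = 0.994). DNA replication genes had a median of -0.25 over 41 members (permutation p = 0.0006, adjusted p = 0.00202), and Orc3 and Rfc5 fell by 1.02 and 0.71 in the authors' deposited table. By the second statistic neither of these falls passed. Mitosis genes had a median of 0.21 over 32 members with no called member (permutation p = 0.0036, adjusted p = 0.0108).

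Replication-dependent histone genes were the second group with more rises than expected. The RNA was polyA-selected, so these rows cover polyadenylated histone transcripts only, and total histone transcripts were not measured. At 48 h 7 of 18 measured members were called as risen and none as fallen, against 0.669 expected called rises (Fisher's exact p = 2.08e-06, adjusted p = 5.62e-05). Called or not, 14 members were higher than at 0 h and 4 lower. The list's median was 0.54 (permutation p = 0.0002, adjusted p = 0.0009). Beside the members named above, Hist1h2bc rose by 1.35 and Hist2h2be by 1.07 in the authors' deposited table. Without marked genes 4 of 15 members were called as risen (Fisher's exact p = 0.00109, adjusted p = 0.0383). None was called at 24 h, when the median was 0.05 (permutation p = 0.594).

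Several lineage marker lists had medians above random lists at 48 h, each with few called members, and endoderm and trophoblast markers did so at 24 h too, with medians of 0.31 and 0.23 (adjusted permutation p = 0.0018 and 0.0243). At 48 h endoderm markers had a median of 0.52 over 17 members (adjusted permutation p = 0.0009), and Gata4 and Gata6 rose by 0.85 and 0.79 in the authors' deposited table. Of these, Gata4 passed the second statistic and Gata6 did not. Trophoblast markers had a median of 0.62 over 12 members, with Tfap2c higher by 1.19 and Ascl2 lower, at -1.78, in the authors' deposited table. Mesoderm markers had a median of 0.65 over 9 members, and Wnt3 was the only called one. Both lists passed at an adjusted permutation p of 0.0009. Immediate early genes had a median of 0.35 over 23 members (adjusted permutation p = 0.00154), with Fosl1 and Fos higher by 1.80 and 0.68 in the authors' deposited table. Fosl1 passed the second statistic and Fos did not. Neural and fibroblast markers did not pass, with medians of -0.10 and -0.15. Neurod1 and the collagen gene Col1a1 were their called members, Col1a1 at 0.89 in the authors' deposited table, and both carry the authors' Dox mark. Only Neurod1 passed the second statistic. Pluripotency genes had a median of 0.14 at 24 h (adjusted permutation p = 0.0385) and 0.01 at 48 h (permutation p = 0.997). Dppa2 stood lower and Tet1 higher among their 29 members, at -0.71 and 0.55 in the authors' deposited table, both called but neither past the second statistic. Primed epiblast markers had a median of -0.23 over 12 members (adjusted permutation p = 0.0937), and the DNA methyltransferase gene Dnmt3a fell by 1.55 in the authors' deposited table.

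Genes of the transcription and RNA processing machinery had medians near 0. CTD kinases and elongation factors, cleavage and polyadenylation factors, and splicing factors all had medians of 0.01 to 0.02 at 48 h, with permutation p values of 0.976, 0.957 and 0.949. Among them Rpap2 and Ssu72, phosphatase genes acting on the polymerase, fell by 1.21 and 0.80, and Cstf3 by 0.58, in the authors' deposited table. The fall of Cstf3 did not pass the second statistic. Of the 2 called CTD kinase and elongation factor genes 1 carries the authors' Dox mark. Cholesterol biosynthesis genes had a median of -0.26 at 24 h (adjusted permutation p = 0.0018) and -0.17 at 48 h (adjusted permutation p = 0.0954), and Nsdhl fell at both times, by 1.03 and 1.31 in the authors' deposited table. Of their 2 called falls at 48 h 1 carries the Dox mark. Cytosolic ribosomal protein genes had medians of -0.12 and -0.09 over 84 members (adjusted permutation p = 0.0027 and 0.0589), and with random lists matched on gene length the adjusted permutation p at 24 h was 0.06. Mitochondrial ribosomal protein genes had medians of -0.06 and -0.13 over 76 members (adjusted permutation p = 0.0679 and 0.0135), and 5 were called as fallen at 48 h. With lists matched on length their adjusted permutation p at 48 h was 0.059. Medians of the integrated stress response, interferon response and glycolysis lists were -0.14, 0.03 and 0.20 at 48 h, with adjusted permutation p values of 0.129, 0.997 and 0.055. No list had more called falls than expected after adjustment at either time by Fisher's exact test. At an unadjusted p of at most 0.05 there was 1 such list at 24 h, primed epiblast markers, and 0 at 48 h.

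**Figure D2:**
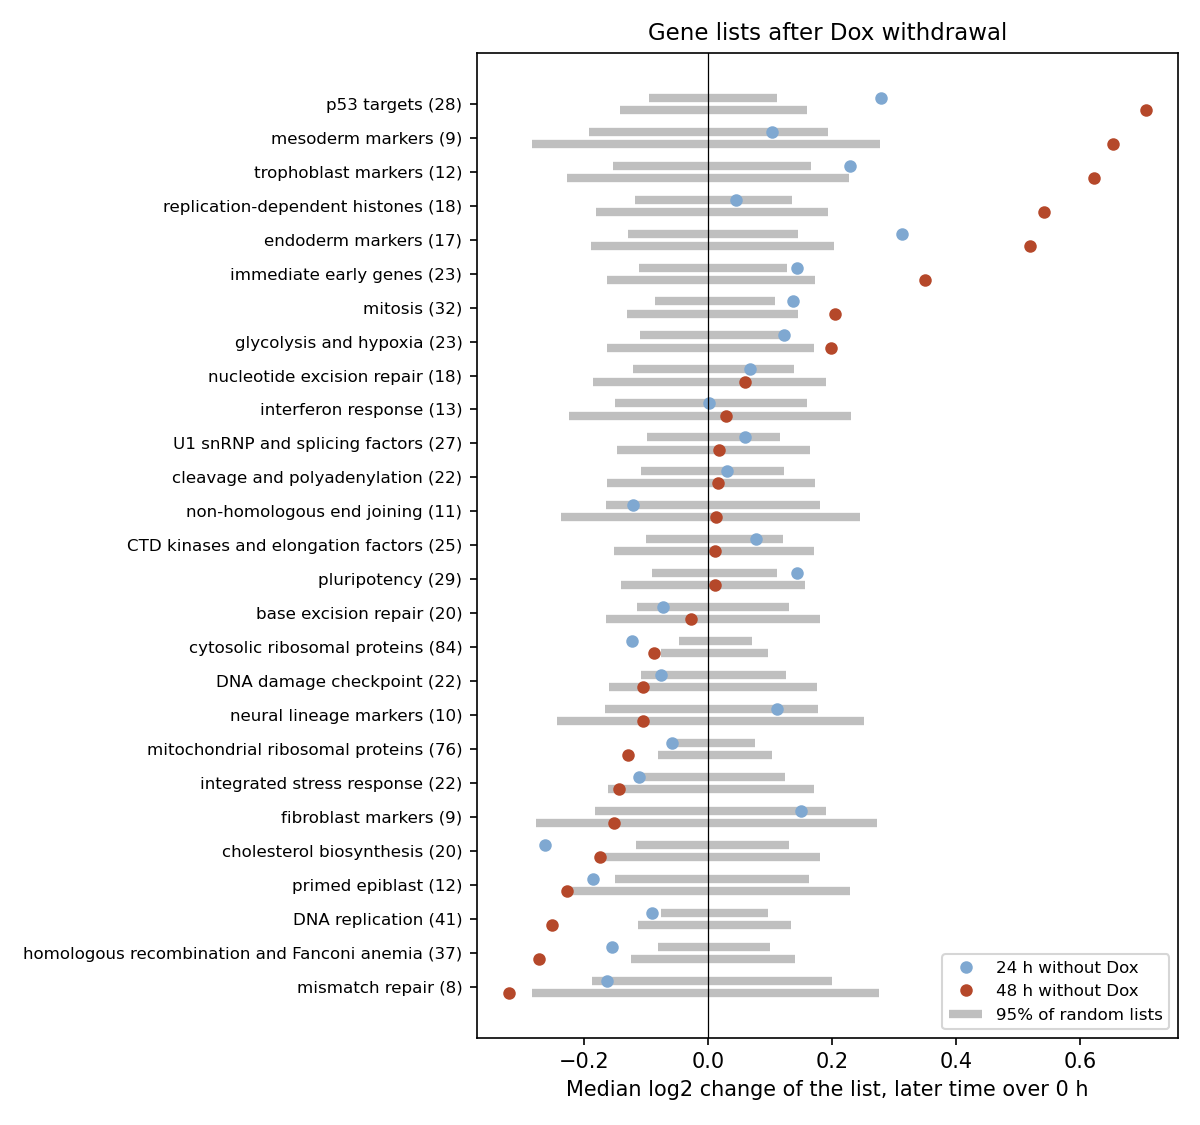
Median log2 change, later time over 0 h, of each gene list with its number of measured members at 48 h, at 24 h (blue) and 48 h (red). Grey bars span 95% of 10000 random lists of the same size. The p53 targets stand highest, at 0.71 at 48 h, and the mismatch repair and homologous recombination lists lowest, at -0.32 and -0.27.

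The 2 times were compared with each other through their calls, since a direct test of 48 h against 24 h needs values per library. Of the called genes with a posterior probability at both times, 73 fell at both and 40 rose at both in the authors' deposited table, and none was called in opposite directions. Independent lists of these sizes would share 3.20 and 1.95 genes. Both times were compared with the same 0 h libraries, and unchanged groups simulated against shared controls gave lists of these lengths an overlap of 28.4 and 18.8 genes on average and at most 41 and 27. That simulation treats the 4 libraries of a group as exchangeable and leaves out the clones and replicates. It also draws every gene independently with the same variance and ranks genes by their difference, not by posterior probability. Genes of unequal variance or correlated genes were not simulated, so its values are no upper limit for unchanged groups. Rapgef4, Duox1, Duoxa1 and Lypd1 were among the genes that fell at both times, and Zfp750 and Plk2 among those that rose. By the second deposited statistic Duox1 and Duoxa1 passed at both times, Lypd1 at neither, and Plk2 did not pass at 24 h. Genes that fell at 24 h had a median log2 change of -0.90 at 24 h and -1.24 at 48 h, and those that rose at 24 h 0.64 and 0.81, in the authors' deposited table; whether the times differ was not tested. Across 12766 genes, which are not independent replicates, the changes at both times had Pearson's r = 0.793 and Spearman's rho = 0.728, and 76.8% of genes had the same sign. Simulated unchanged groups gave r = 0.50 and 66.7% on average, and at most 0.52 and 67.6%. Part of the excess over independent lists may come from the shared controls, and a covariance due to them could not be computed without values per library.

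Because the series title names intronic polyadenylation, changes were set against the genomic length of each gene. Shorter genes were slightly lower. The Spearman correlation across genes was 0.0798 at 24 h and 0.0884 at 48 h (permutation p = 1e-05, the smallest 100000 permutations can give). At 48 h 5.53% of the shortest quartile were called as fallen and 3.12% as risen, against 3.87% and 4.46% of the longest. Falls made up 3.51% of the second and 3.03% of the third quartile, so their share did not drop steadily with length. Falls were more frequent in the shortest than in the longest quartile (Fisher's exact p = 0.00253, adjusted p = 0.0101 over 4 such tests) and rises less frequent (Fisher's exact p = 0.00743, adjusted p = 0.0149). At 24 h 0.669% and 0.797% fell, a difference not past the threshold (Fisher's exact p = 0.658, adjusted p = 0.877). Among called genes alone the correlation was 0.004 at 24 h (permutation p = 0.965) and 0.027 at 48 h (permutation p = 0.407). By the second deposited statistic the shortest and longest quartiles held equal shares of falls at 48 h, 2.22% each. How the number of introns relates to the change was not analysed here.

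**Figure D3:**
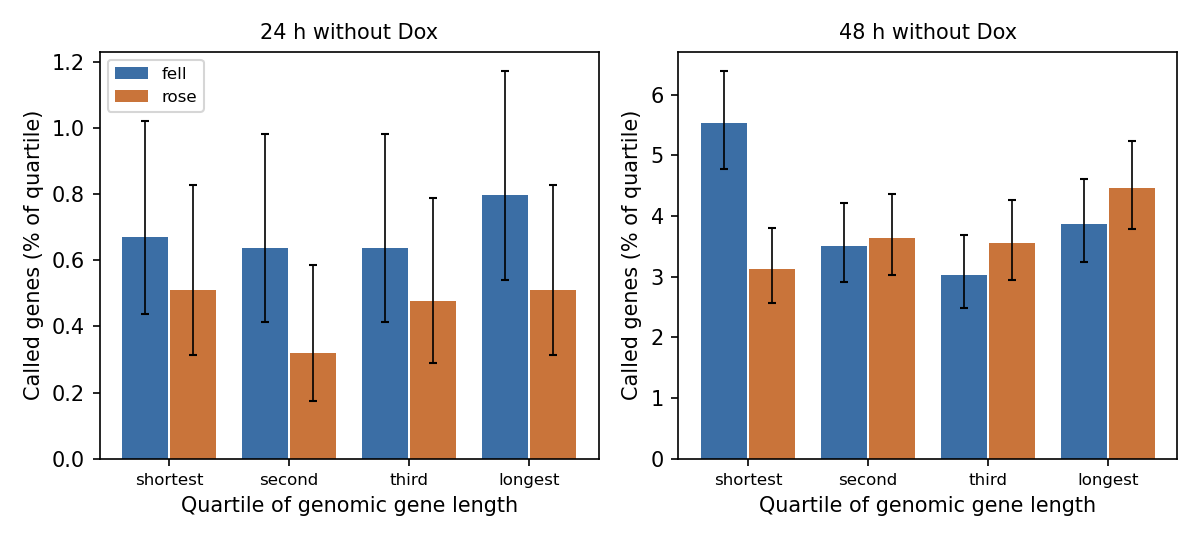
Percent of genes called as fallen (blue) or risen (orange) in each quartile of genomic gene length, at 24 h (left) and 48 h (right, with its own scale). Error bars are 95% Wilson intervals and cover counting error over genes only. At 48 h the shortest quartile holds the highest share of falls, 5.53%.

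What Dox withdrawal alone does was the question of the parental cells. Their values are not analysed here, and the difference between knockout clones and parental cells was not tested. The authors' deposited table marks 3 called genes at 24 h and 149 at 48 h as a Dox effect, without defining it. At 24 h these were Alpk3, Foxn4 and Ttc7. Of the marked genes at 48 h 83 fell and 66 rose, Pde9a, Neurod1, Hist2h3c1 and Zfp750 among them. Without marked genes 410 fell and 395 rose at 48 h.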

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

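The second deposited statistic holds a signal that the calls do not use. At 48 h it passed 35 genes that the posterior probability did not call, of which 25 fell and 10 rose, and 11 of them had a posterior probability under 0.001 in the authors' deposited table. Creb3l4, for example, stood at -1.89 with an adjusted p of 0.0232 by the authors' second statistic and a posterior probability of 3.04e-18 in the authors' deposited table. Of the calls of the second statistic 92.5% were also calls of the posterior probability. No explanation was tested.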

How the results depend on the processing

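No paired analysis was possible because the authors' deposited table has no column per library. For the same reason, leaving out libraries, single clones, a clone term, other normalizations, filters and pseudocounts, and filters or matching on expression were not run, and neither were the posterior fold change, exonic length and intron number. The second deposited statistic, removal of marked genes, protein-coding genes alone and neighbours without list genes were chosen after seeing the data. Counts of calls stayed within 1.5 times at a posterior probability of 0.99, at 1.5-fold, without predicted names and without marked genes. At 2-fold or more the calls numbered 37 at 24 h (33 fell, 4 rose) and 332 at 48 h (187 fell, 145 rose), fewer by construction, and 29 fell and 4 rose at both times. With the second statistic they numbered 21 at 24 h (19 fell, 2 rose) and 465 at 48 h (249 fell, 216 rose), and 18 fell and 2 rose at both times; the cause was not tested. The share of calls at 24 h that fell moved from 60.1% to 90.5% with that statistic. The p53 and histone lists were the 2 with more rises at 48 h, and both passed under each of the 4 alternatives for calls. Without marked genes, which are all called genes, their rises went from 14 to 4 and from 7 to 4, each at an adjusted Fisher's exact p of 0.0383. Among called genes alone the correlation with length was 0.00372 at 24 h and 0.027 at 48 h, no longer past the threshold, over fewer genes. With random lists matched on length, 51 of the list medians kept their side of the threshold, 2 were no longer past it, both of ribosomal protein lists, and 1, of immediate early genes at 24 h, came past it. What depth limits is unknown here.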

Other observations

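The tests on neighbours and on the Dox mark were chosen only after the result was seen. So were the protein-coding and second-statistic settings used for gene length, whose outcomes had not been seen when the tests were set.

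Genes called at 48 h, and those that fell at 24 h, lay beside each other along the chromosomes more often than random sets did on average, while rises at 24 h gave 0 adjacent pairs against 0.256 on average (permutation p = 1). At 48 h 33 adjacent pairs of table genes fell, against 18.9 on average and at most 37 in 10000 random draws (permutation p = 0.001, adjusted p = 0.004 over 4 tests). Pairs that rose numbered 27, against 16.1 on average and at most 34 (permutation p = 0.0067, adjusted p = 0.0134). Single draws thus held more pairs than were seen, but such draws were rare, and both counts were past the threshold. For the falls at 48 h this argues against random placement as the whole cause. For the rises the count without genes of the fixed lists, given below, was not past the threshold, so random placement stays open there. A few pairs at 48 h overlap in the annotation, Tlcd1 with Rpl23a and Ptprv with Ptpn7 among them. Most pairs of either direction do not overlap, so reads counted for an overlapping neighbour could not account for those. No further test of this was made at 48 h. Of the rising pairs 4 were pairs of histone genes. Without genes of the fixed lists, an alternative chosen after seeing the data, 28 pairs fell, against 17.2 (permutation p = 0.0091, adjusted p = 0.0364), and 20 rose, against 13.9, no longer past the threshold (permutation p = 0.0649, adjusted p = 0.13). Rising neighbours included Wnt6 and Wnt10a, both Wnt ligands, Tap1 and Tap2, the peptide transporter of antigen presentation, and Ltb4r1 and Ltb4r2. These pairs were chosen after their values were seen.

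Chosen after their values were seen, and not an adjacent pair of the kind counted above, Lefty1 and Lefty2, inhibitors of Nodal signalling, fell at 24 h to 28.5% and 42.9% of their 0 h levels in the authors' deposited table, and at 48 h they stood at 58.3% and 52.4% there, neither called.

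Among the called falls at 24 h 3 adjacent pairs stood out, Duoxa1 with Duox1, Th with Ascl2, and Ascl2 with Tspan32. Reads counted for an overlapping neighbour could account for the first pair, since 1 of the 3 pairs overlaps in the annotation, but not for the run from Th to Tspan32. Draws of random placement along the chromosomes gave 0.574 pairs on average and at most 6 (permutation p = 0.021, adjusted p = 0.028). The count was past the threshold, but it rests on only 3 pairs, and those of the run share Ascl2. Random placement is therefore not settled at 24 h. Without genes of the fixed lists, which hold Ascl2, 1 pair remained (permutation p = 0.402). Both pairs of the run hold Ascl2, so its removal took both away by construction and does not bear on random placement. Of the 5 genes 0 carry the Dox mark, against 5 of the other 81 falls (Fisher's exact p = 1), too few to decide on an effect of Dox itself as marked by the authors. No biological explanation was tested.

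Falls at 48 h were more frequent in the shortest than in the longest quartile of gene length. Small ribosomal protein genes do not account for it, since without them 5.40% of the shortest and 3.89% of the longest quartile fell (Fisher's exact p = 0.00598). Non-coding and pseudogene entries do not account for it either, with 5.58% of the shortest quartile of protein-coding genes falling (Fisher's exact p = 0.00227). A candidate explanation for the shares of calls is the posterior probability caller, since by the second statistic 2.22% of both quartiles fell (Fisher's exact p = 1). Values that do not use the caller ran the same way, by a small amount. At 48 h the Spearman correlation over all genes was 0.0884 (permutation p = 1e-05). The median log2 change was -0.04 in the shortest and 0.04 in the longest quartile. The caller does not account for that slight shift. No biological explanation was tested.

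Of the 14 p53 targets that rose at 48 h 10 carry the Dox mark, against 139 of the other 940 called genes (Fisher's exact p = 3.75e-06, adjusted p = 1.87e-05 over 5 lists). Marks drawn at random within bins of the second statistic gave 2.46 marked targets on average and at most 9, which argues against the strength of evidence as the whole cause. Draws within bins of the size of the change gave 2.21 on average and at most 8 (permutation p = 0.0001 in both, the smallest these draws can give). An effect of Dox withdrawal on p53 targets without loss of Cdk12 may explain the marks and stays open, untested, because the mark is undefined and the parental libraries are not analysed here.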
